A study of Mus musculus with 6 samples.

How the data were processed

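The 6 libraries were prepared from intestinal tissue of mice, 3 from the cold water group and 3 from the control group. Per the labels' protocols, total RNA with an integrity number over 7 was depleted of ribosomal RNA from about 5 µg, fragmented and reverse-transcribed, and libraries with a mean insert of 300 bp (spread 50 bp) were read from both ends on an Illumina instrument. Per the submitters' processing notes, the tools were cutadapt 1.9, FastQC 0.10.1, HISAT2 2.0.4, StringTie 1.3.4d, edgeR and DESeq2. The role of each tool, the genome build and whether the libraries keep the strand are not given in the sources used here. The labels say that the mice were divided into groups, and nothing in them says that each library comes from a separate animal.

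The deposited table holds 142604 transcripts with Ensembl mouse IDs. Per the file headers, the authors gave an FPKM value for each transcript and library. In the values themselves, transcripts with a count of 0 were listed at 0.0001 FPKM. The lowest FPKM, 1e-06, was held by 11 to 27 transcripts of a library. Per the file headers, the authors also gave an estimated count for each transcript and library. The deposited estimated counts were whole numbers equal, within a tolerance of 0.02, to the FPKM times the transcript length and a constant of the library, rounded up, for 100% of the values checked. They were therefore estimates from coverage and not numbers of fragments. Low values gathered at a step of 3.75 to 3.77 counts, taken here as the worth of 1 fragment. With this step the totals of 72690433 to 78668871 counts stand for about 19332600 to 20922600 fragments. Because a count is worth less than a fragment, any interval from counts is narrower than the fragments allow, and intervals cover counting error only. Of the transcript IDs, 141374 were found in GENCODE M21, and 99.7% of those had coordinates identical to its GRCm38 positions. Coordinates in the text are those of the deposited table.

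The estimated counts of a gene's transcripts were summed by gene symbol, and by gene ID where no symbol was given. There were 55401 gene IDs, and 120 symbols had more than 1 ID. Genes and transcripts with a mean of at least 1 FPKM over the 6 libraries were kept, 12940 and 21041 respectively, and the others were left out as too low to test. Cold water was compared with control in 1 model per level with group as its sole term, by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM scaling factors of 0.895 to 1.11 and Benjamini-Hochberg adjustment at a threshold of 0.05. The design fixed before the data were examined named limma on log2(FPKM + 1), since the table was described as FPKM. As the table also held estimated counts, the count test became the main test and limma 3.58.1 an alternative. Because these counts are coverage estimates, this was a choice and not required by the design. Which genes passed depended on it. Levels are given in CPM (counts relative to the scaled library total) as group mean ± SD over 3 libraries, and log2 differences are cold water minus control.

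Genes were named by a rule set in advance. It took up to 12 genes in each direction with the largest change among those that passed and whose groups did not overlap, filled with the genes of smallest unadjusted p without overlap, given as values alone. It also took 17 genes of cold response, barrier, digestion and intestinal segment, and the 2 to 4 members of smallest unadjusted p in each gene list described. For transcripts it took up to 5 in each direction past the threshold. Genes named outside the rule, such as overlapping neighbours, isoforms of called genes and segment markers, were chosen after their values were seen. Some genes that the rule took are not reported here.

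In all, 51 gene lists of functions and cell types were fixed in advance, with 1367 entries of which 1346 matched a symbol of the table and 32 matched by gene ID under another symbol. The 47 lists with at least 5 kept genes were tested by camera with a preset correlation of 0.01, beside camera with an estimated correlation and fry, each with adjustment over the lists. Segment markers were summarised as the median FPKM of a list per library, with no test. Libraries were also compared by Pearson correlation and principal components of log2 CPM.

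The tests were tried on simulated counts drawn from the means and library sizes of the real libraries with 200 genes changed. Of 12940 genes, 19% of those changed 2-fold, 85.5% of those changed 4-fold and 97.5% of those changed 8-fold were recovered, with 1, 4 and 9 false calls, and with no change there were 0 false calls. For transcripts changed 8-fold the share recovered was 29.5% with 2 false calls. With no change, 0 of the 47 lists were called. The simulated genes were drawn independently of each other, so this does not show how often lists of correlated genes are called falsely. The shares recovered hold for 200 changed genes, and with fewer the adjustment is stricter.

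Alternatives covered the pseudocount, the filter on low values, scaling between libraries, the variance model, library weights, the replicate number as a block, each library left out in turn, the threshold, the most abundant transcript in place of the sum, and the list test. DESeq2 1.42.0, summing by gene ID, counts divided by the step of 1 fragment, and library totals without scaling factors were added after seeing the data. All 10 splits of the 6 libraries into groups of 3 were fitted as well.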

Results

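RNA was measured in intestinal tissue of mice given 1 ml of water by gastric gavage once a day for 14 days, per the labels. In the cold water group (n = 3 libraries) the water was at 0 to 4 °C and was given at 8 am. In the control group (n = 3 libraries) it was at 20 to 25 °C and was given at 9 am. All mice were housed at 22 °C. Each library was made from total RNA after removal of ribosomal RNA, so transcripts without a poly(A) tail were read as well. The total estimated count was 78668871, 73280401 and 72860893 in cold water 1, 2 and 3. It was 74547280, 72690433 and 78148001 in control 1, 2 and 3. The smallest step of the counts put these totals at about 19332600 to 20922600 fragments per library. Of 142604 transcripts in the table, 54.3 to 59.6% had a count of 0 in a library. In all, 12940 genes and 21041 transcripts reached a mean of 1 FPKM over the 6 libraries and were tested.

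The markers of small intestinal absorptive cells were abundant in all 6 libraries and those of the colon and of the far ileum were low. No list of markers particular to the jejunum was read. The sample characteristics in the labels give proximal jejunum and the design text gives colon, so the levels of segment markers were read first. Apoa1, an apolipoprotein of chylomicrons, had a mean of 11357 ± 1839 FPKM (SD, n = 6). Lactase (Lct) had 312 ± 64.4 FPKM, sucrase-isomaltase (Sis) 522 ± 74.2 FPKM and the sodium-glucose cotransporter Slc5a1 634 ± 61.1 FPKM. All 31 small intestinal enterocyte genes reached 1 FPKM in each library, and the median gene of the list lay between 237 and 405 FPKM. Of the 31 colonocyte and colon genes, 16 to 18 reached 1 FPKM in a library, with a median of 1.40 to 3.04 FPKM. Carbonic anhydrase 1 (Car1), abundant in colonocytes, had a mean of 0.988 FPKM. The epithelial sodium channel subunit Scnn1b and the posterior homeobox gene Hoxb13 had means of 0.00330 and 0.0609 FPKM. Among colon list genes that small intestine also expresses, Krt20 and Car4 had means of 1123 and 259 FPKM. The ileal list reached a median of 67.0 to 106 FPKM through Guca2b (3076 FPKM), Cyp4f14 (371 FPKM) and the bile acid exporter subunits Slc51a (126 FPKM) and Slc51b (111 FPKM). The ileal bile acid binding protein Fabp6 (0.211 FPKM), the ileal bile acid transporter Slc10a2 (0.125 FPKM) and the enterokine Fgf15 (a count of 0 in all 6 libraries) were low. The duodenal list had a median of 0.997 to 2.07 FPKM, with Gata4, a transcription factor of the proximal intestine, at 44.4 FPKM and the Brunner gland mucin Muc6 at 0.215 FPKM.

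**Figure D1:**
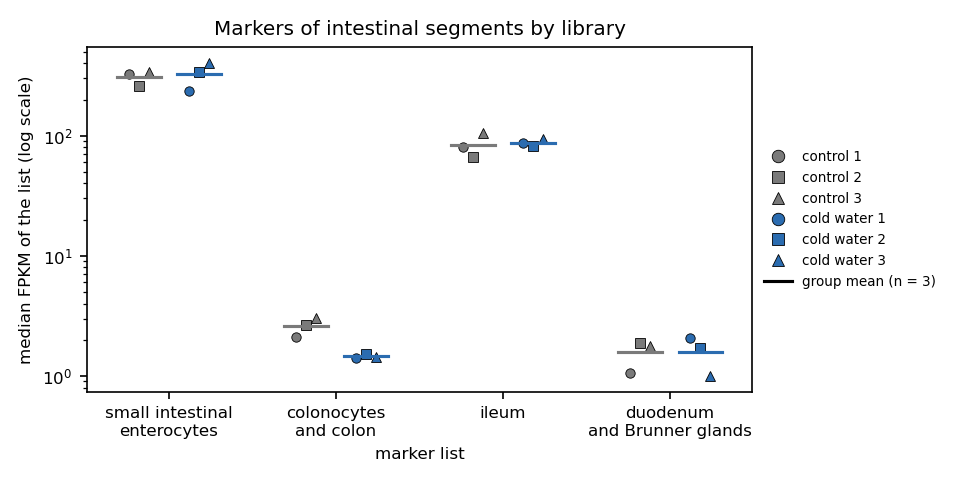
Median FPKM (log axis) of the genes of 4 marker lists in each of the 6 libraries, cold water in blue and control in grey. The median of small intestinal enterocyte genes lay at 237 to 405 FPKM and that of colon genes at 1.40 to 3.04 FPKM.

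Libraries of the same group were about as alike as libraries of different groups. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.933 to 0.959 within groups (mean 0.947). Between groups they were 0.926 to 0.967 (mean 0.945). The first 3 principal components held 34.0, 27.1 and 16.8% of the variance. Cold water 1 stood apart by its immunoglobulin genes, which took 1.15% of its counts (exact 95% binomial interval over its fragments 1.14 to 1.15%, for counting error only) against 0.248 to 0.386% in the other 5 libraries. Mitochondrially encoded genes took 8.18 to 12.6% of the counts, and nuclear genes that copy mitochondrial sequence, such as Gm29216 and Gm28661, took a further 2.84 to 4.03%.

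Cold water against control, gene by gene, addresses which genes of the intestine respond to repeated intake of water near freezing. Tspan14, a tetraspanin that binds the protease ADAM10 and helps it to the cell surface, rose 4.41-fold, from 9.48 ± 0.243 CPM (counts relative to the scaled library total; SD, n = 3) in controls to 41.8 ± 1.81 CPM in cold water. Col4a3bp, which encodes the ceramide transfer protein that carries ceramide from the endoplasmic reticulum to the Golgi, fell from 46.8 ± 2.09 to 13.0 ± 0.993 CPM. Ap1ar, whose product gadkin links the AP-1 vesicle coat to a kinesin motor, fell from 101 ± 15.0 to 27.9 ± 2.32 CPM. Among genes of unknown function, the microRNA gene Gm22758 rose from a count of 1 in each control library to 58 to 120 in the cold water libraries, and the predicted gene Gm15743 fell from 5.40 ± 0.601 to 0.470 ± 0.129 CPM. These were the 5 genes, of 12940 tested, that passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2 up and 3 down.

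The log2 fold change of Tspan14 (ENSMUSG00000037824, chromosome 14, 40906445 to 40966807) was 2.14 with a standard error of 0.13 and an edgeR adjusted p = 0.0138. That of Col4a3bp (ENSMUSG00000021669, chromosome 13, 96542618 to 96640167) was -1.84 with a standard error of 0.14 and an adjusted p = 0.0210. That of Ap1ar (ENSMUSG00000074238, chromosome 3, 127807007 to 127837523) was -1.86 with a standard error of 0.16 and an adjusted p = 0.0273. For Gm22758 (ENSMUSG00000076230, chromosome 2, 156410929 to 156411024) the ratio of summed counts was 89.9, with an exact 95% interval for counting error of 30.4 to 439. Its edgeR adjusted p was 0.0225, and the call ended when counts were divided by the worth of a fragment (adjusted p = 0.310) or with no filter on low values (adjusted p = 0.0606). For Gm15743 (ENSMUSG00000086645, chromosome 16, 31427876 to 31429776) the log2 fold change was -3.52 with a standard error of 0.33 and an adjusted p = 0.0453. All coordinates are those of the deposited table. At Tspan14 most of the rise lay in the isoform ENSMUST00000047652 (28.0 ± 0.366 against 0.609 ± 0.370 CPM). Its other isoforms together had a log2 difference of 0.63. At Col4a3bp the isoform ENSMUST00000109444 held 45.8 ± 1.61 CPM in controls and 4.90 ± 2.11 CPM in cold water. Its other isoforms together held 1.00 ± 0.704 and 8.14 ± 1.91 CPM. At Ap1ar the isoform ENSMUST00000051737 held 90.3 ± 25.2 CPM in controls and 23.4 ± 2.92 CPM in cold water.

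The short gene Gm22758 lies inside Gm14173 on the same strand, which had 2.55 ± 0.0981 CPM in controls and 0.938 ± 0.164 CPM in cold water. Counts summed over both genes differed by -0.28 on the log2 scale. The rise of Gm22758 is therefore uncertain. Gm15743 overlaps Bdh1, an enzyme of ketone body metabolism, on the opposite strand. Bdh1 itself differed by -0.020, and the sum over both by -0.053. Gm15743 held 1.38% of the counts of the locus, so this sum says little about it. Whether the libraries keep the strand is not given, so the fall of Gm15743 is uncertain as well. Ap1ar, with 57.1% of the counts of its locus, overlaps 3 genes, the largest being Tifa on the opposite strand. Tifa had 33.7 ± 2.58 CPM in cold water and 62.9 ± 45.3 CPM in controls. The sum over Ap1ar and these 3 genes differed by -1.41. With the strand unknown, the size of the fall of Ap1ar is uncertain too. None of the 5 genes passed with any 1 of the 6 libraries left out, when 0 to 1 genes were called. Their edgeR adjusted p then lay between 0.060 (Tspan14) and 0.296 (Gm15743), with the same directions. At an unadjusted p under 0.05 there were 648 genes (373 higher and 275 lower in cold water) where chance gives 647. Groups did not overlap for 10.5% of genes, where chance gives 10%. DESeq2 called 71 genes and limma on log2(FPKM + 1) called 3, which were Tspan14, Gm22758 and Cdipt. The calls of Col4a3bp, Ap1ar and Gm15743 were lost with limma.

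**Figure D2:**
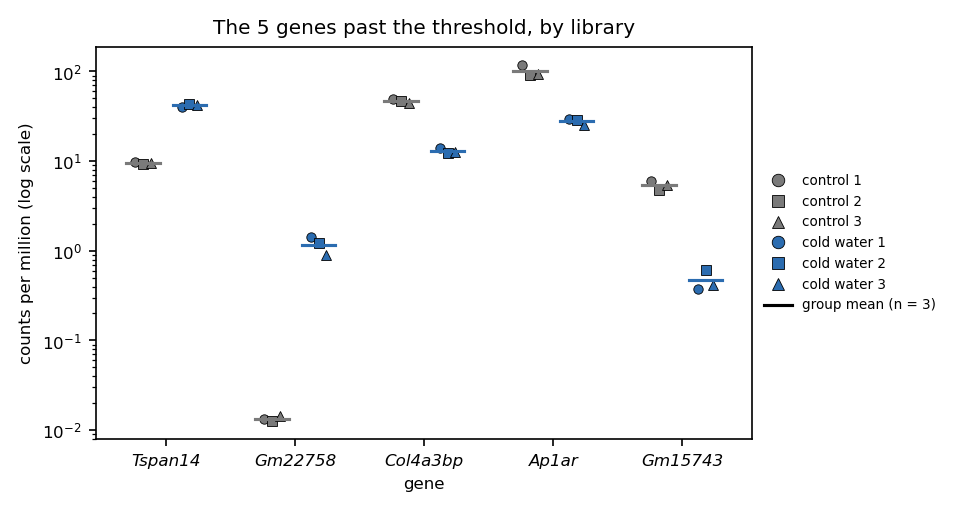
CPM (log axis) in each of the 6 libraries of the 5 genes that passed the edgeR test, cold water in blue and control in grey, with group means as bars. Tspan14 lay at 39.9 to 43.5 CPM in cold water and at 9.25 to 9.73 CPM in controls.

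The genes with the next smallest p-values whose groups did not overlap did not pass the test, and their values are given without a claim of change. Cdipt passed in 10 of 24 alternatives, limma on log2(FPKM + 1) and DESeq2 among them. On the higher side in cold water stood Cdipt, the phosphatidylinositol synthase, at 206 ± 37.2 against 63.9 ± 10.6 CPM (SD, n = 3). The vasohibin chaperone Svbp stood at 9.05 ± 2.74 against 2.28 ± 0.336 CPM, and Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, at 61.6 ± 9.11 against 36.4 ± 0.349 CPM. The others on this side were the immunoglobulin kappa variable gene Igkv6-32 (log2 difference 2.34), the stress-activated kinase Taok1 (1.18), the hyaluronan-binding gene Cemip (2.19), the axonemal dynein gene Dnah2 (1.74), the calcium-binding gene S100a11 (0.86), the sulfotransferase gene Sult6b2 (0.85) and the phosphatase catalytic subunit Ppp6c (0.66). On the lower side stood the water channel Aqp8 at 1.31 ± 0.171 against 5.09 ± 1.23 CPM and the alcohol dehydrogenase Adh4 at 14.2 ± 2.17 against 33.1 ± 2.76 CPM. Cd47, a surface protein that restrains phagocytosis, stood at 73.7 ± 3.98 against 119 ± 14.5 CPM. Others on this side included the metallopeptidase gene Adam1a (log2 difference -2.05), the predicted gene Gm18194 (-1.78), the lens filament gene Bfsp1 (-0.97), Tmem254c (-0.71) and the elongation factor gene Tcea3 (-0.70). The edgeR adjusted p of these genes ran from 0.135 (Cdipt) to 0.866 (Cd47 and Tcea3).

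Genes singled out in advance for cold response, barrier and digestion lay close to their control levels. The cold-inducible RNA-binding protein genes Rbm3 (121 ± 38.6 against 101 ± 11.6 CPM, SD, n = 3) and Cirbp (17.4 ± 2.96 against 18.2 ± 9.94 CPM) differed by less than their spread. The cold-sensing channel gene Trpa1 had a mean of 0.659 FPKM and Trpm8 a count of 0 in all 6 libraries, so neither was tested. The tight junction genes Tjp1 (log2 difference 0.30), Ocln (0.14) and Cldn2 (0.22), the main intestinal mucin Muc2 (0.050) and the antimicrobial lectin Reg3g (0.16) did not pass. Neither did the serotonin-synthesis gene Tph1 (0.36), the hormone gene Cck (-0.26), Slc5a1 (0.041), Lct (0.15) or Sis (-0.047). Their edgeR adjusted p ran from 0.899 (Tjp1) to 0.995 (Muc2). In simulated libraries of this size, the same test recovered 19% of 200 genes changed 2-fold and 85.5% of those changed 4-fold. Changes of 2-fold were thus mostly out of reach. The share for 4-fold holds for 200 changed genes and may be lower here, since fewer changed genes make the adjustment stricter. In the real libraries Tspan14 passed at 4.41-fold. Cemip at 4.58-fold (edgeR adjusted p = 0.788) and Igkv6-32 at 5.07-fold (edgeR adjusted p = 0.510) did not.

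Transcript by transcript, the comparison asks whether cold water changed which isoforms were present. The transcripts that fell were single isoforms, and for all but 0610005C13Rik the log2 difference of the whole gene lay between -0.23 and 0.18. ENSMUST00000101032 of Marchf8, a ubiquitin ligase that removes immune receptors from the cell surface, fell from 123 ± 20.9 to 4.21 ± 0.723 CPM (SD, n = 3). The isoform ENSMUST00000203193 of the same gene stood at 0.0190 ± 0.0329 CPM in controls and 122 ± 14.9 CPM in cold water. ENSMUST00000179728 of the ribonuclease gene Rnaset2b fell from 67.7 ± 6.30 to 0.528 ± 0.136 CPM. Its isoform ENSMUST00000089119 stood at 24.8 ± 1.62 and 76.6 ± 11.3 CPM. ENSMUST00000001116 of Luzp1, a leucine zipper protein of the actin cytoskeleton, fell from 48.5 ± 25.9 to 0.105 ± 0.0200 CPM. Last, ENSMUST00000210569 of the antisense gene 0610005C13Rik fell from 88.3 ± 5.03 to 17.7 ± 0.980 CPM.

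Of 21041 transcripts, 6 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among them were these 4 and the single transcript of Gm22758 (ENSMUST00000102275), which rose with a log2 fold change of 6.30 and an adjusted p = 0.0411. The log2 fold change was -7.00 for Rnaset2b (standard error 0.31, adjusted p = 0.0176), -4.87 for Marchf8 (0.23, 0.0176), -2.32 for 0610005C13Rik (0.13, 0.0267) and -8.83 for Luzp1 (0.61, 0.0498). These genes themselves did not pass, with gene-level log2 differences of -0.23 for Rnaset2b, 0.087 for Marchf8, -0.88 for 0610005C13Rik and 0.18 for Luzp1. No gene had called transcripts in both directions. Rnaset2b has a near-identical copy, Rnaset2a, so reads of these genes are uncertain. The leading isoform was not the same in all 6 libraries for 4195 of 10614 genes with more than 1 isoform (39.5%). No transcript was called without cold water 1, cold water 2, cold water 3, control 1 or control 2, and 10 were called without control 3. DESeq2 called 585 and limma 23, and 996 transcripts had an unadjusted p under 0.05 where chance gives 1052.

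**Figure D3:**
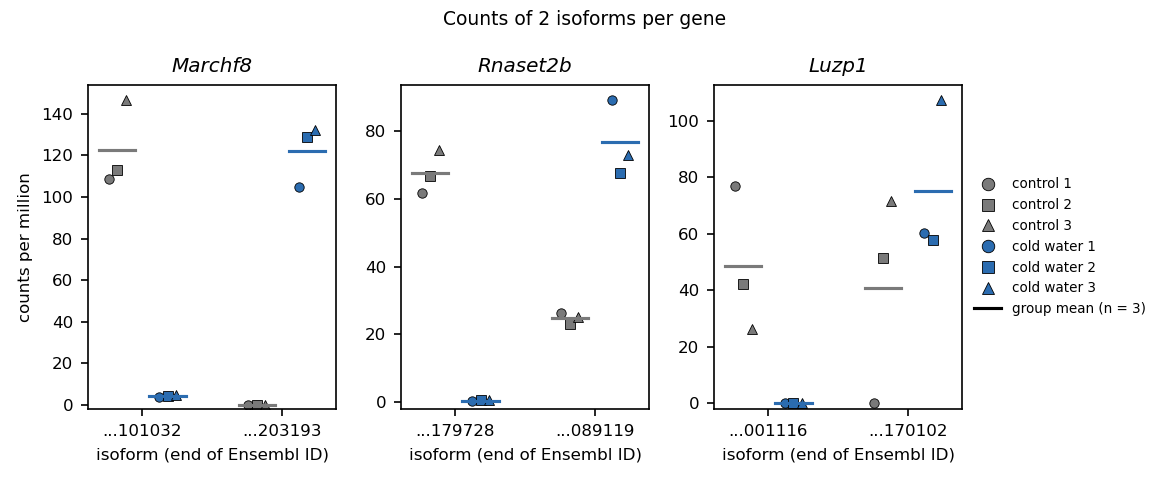
CPM (linear axis) in each of the 6 libraries for the called isoform and another isoform of Marchf8, Rnaset2b and Luzp1, cold water in blue and control in grey. For Marchf8 the called isoform lay at 108 to 147 CPM in controls and at 3.57 to 4.99 CPM in cold water.

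Gene groups fixed in advance were compared as sets, which asks whether genes of a shared function or cell type moved together. The group that stood out was the interferon response. Of its 51 measured genes, 49 were lower in cold water, with a median log2 difference of -1.05, which is 2.06-fold lower. Xaf1, an interferon-induced promoter of apoptosis, had 17.9 ± 2.65 CPM in cold water and 69.8 ± 36.4 CPM in controls (SD, n = 3). The antiviral genes Ifit3 (16.3 ± 4.89 against 112 ± 85.6 CPM), Ifi44 (6.08 ± 2.10 against 29.9 ± 18.5 CPM) and Ifit3b (4.39 ± 0.457 against 27.9 ± 22.6 CPM) were likewise lower in every cold water library than in any control. No member passed over all genes tested and 17 passed when adjusted over the list alone, all lower; 13 had groups without overlap. The list was lower as a set by camera with a preset correlation of 0.01 (adjusted p = 9.14e-35 over 47 lists), but not with the correlation estimated from the data (adjusted p = 0.928 with an estimated correlation). The mean of the list relative to all 6 libraries was -0.36, -0.48 and -0.65 in cold water 1, 2 and 3 and 0.61, -0.27 and 1.15 in control 1, 2 and 3. Control 2 thus lay near the cold water libraries.

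Genes of MHC class I antigen presentation, many of which interferon induces, were lower by less. The list holds class I molecules as well as genes that load peptides onto them. Of 23 measured, 18 were lower, with a median of -0.32. The peptide transporter subunit Tap2 had 102 ± 2.94 CPM in cold water and 149 ± 5.21 CPM in controls (SD, n = 3) and the immunoproteasome subunit Psmb10 had 163 ± 7.58 and 249 ± 20.9 CPM. None of the 23 passed over all genes, and these 2 did when adjusted over the list alone. The proteasome activator Psme2 (log2 difference -0.48) and the transporter subunit Tap1 (-1.21) did not. The set was lower by camera (adjusted p = 3.95e-08), but not with a fitted correlation (adjusted p = 0.928 with an estimated correlation). MHC class II genes did not pass (median -0.26, mean 0.37, adjusted p = 0.629), with H2-Ob and H2-Oa, the regulators of peptide loading in B cells, at 3.74 and 2.20. Both were high in cold water 1 alone, H2-Ob at 22.4 CPM against 0.285 to 1.09 CPM in the other 5 libraries and H2-Oa at 9.74 against 0.288 to 0.842 CPM. Without cold water 1 the median of the list was -1.30, and camera called it lower (adjusted p = 1.03e-05; adjusted p = 0.907 with an estimated correlation). It was also called lower without control 1 (median -0.69, adjusted p = 0.0158; adjusted p = 0.996 with an estimated correlation).

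Genes of B cells and plasma cells were higher in cold water, with a median log2 difference of 2.38 and 23 of 24 measured genes higher. The immunoglobulin constant genes Iglc1 (74.2 ± 59.1 against 10.7 ± 2.05 CPM, SD, n = 3), Ighg2b (119 ± 161 against 8.44 ± 1.79 CPM) and Ighg2c (41.6 ± 31.8 against 9.46 ± 4.38 CPM) led the list. The receptor gene Ighd of naive B cells had 20.6 ± 33.8 against 0.469 ± 0.150 CPM. No member passed over all genes and Iglc1 alone did when adjusted over the list alone. The set was higher by camera (adjusted p = 1.67e-12), but not with a fitted correlation (adjusted p = 0.993 with an estimated correlation). Without cold water 1, the library rich in immunoglobulin, its median was 0.45 and the list still passed with the preset correlation (adjusted p = 1.51e-05), but not with an estimated correlation (adjusted p = 0.907 with an estimated correlation). T cell and natural killer cell genes (18 of 20 higher, median 0.77) passed camera (adjusted p = 9.42e-05; adjusted p = 0.993 with an estimated correlation), with the adhesion receptor Cd2 at 2.51, Trac at 1.37 and Cd4 at 1.76. Macrophage and dendritic cell genes (12 of 13 higher, median 0.39), among them the growth factor receptor Csf1r (0.74) and the complement gene C1qc (0.56), passed too (adjusted p = 0.0393; adjusted p = 0.993 with an estimated correlation). Neither list had a member that passed over all genes or when adjusted over the list alone. The T cell call was lost without cold water 1 (median 0.22) or control 2 (0.54), and the macrophage call without cold water 1 (0.0022), control 1 (0.38) or control 3 (0.44). Relative to all 6 libraries, the B cell mean was 2.75, -0.69 and 0.25 in cold water 1, 2 and 3. It was -0.85, -0.54 and -0.91 in control 1, 2 and 3. The T cell mean was 1.24, -0.57 and 0.29 in cold water and 0.027, -0.73 and -0.26 in control, in the same order. Cold water 2 thus lay below control 2 for B cells and below control 1 and control 3 for T cells.

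Inflammatory signalling and antimicrobial genes were higher as sets by a smaller margin with the preset correlation only (adjusted p = 0.993 with an estimated correlation for each). Of 24 measured cytokine, chemokine and NF-kB target genes, 19 were higher, with a median of 0.53. Tnfaip3, a brake on NF-kB, had 15.5 ± 8.92 CPM in cold water and 3.66 ± 0.640 CPM in controls (SD, n = 3). The chemokine gene Ccl20 had 12.1 ± 12.7 and 2.62 ± 1.15 CPM, Nfkb1 differed by 0.50, and the inflammasome sensor Nlrp6 was lower, at -0.60. Of 25 Paneth cell and antimicrobial genes, 20 were higher, with a median of 0.24. They were led by the hydrogen peroxide producing oxidase Duox2 (24.9 ± 7.64 against 10.5 ± 1.75 CPM), the angiogenin Ang4 (175 ± 69.1 against 92.8 ± 21.9 CPM) and Nos2 (35.9 ± 53.0 against 2.64 ± 1.38 CPM). Nos2 was carried by cold water 3 (97.0 CPM), with 9.17 and 1.59 CPM in cold water 1 and 2. No member of either list passed over all genes or when adjusted over the list alone. Camera gave the cytokine list an adjusted p = 0.0114 (adjusted p = 0.993 with an estimated correlation) and the Paneth list an adjusted p = 0.00361 (adjusted p = 0.993 with an estimated correlation). The cytokine call was lost without cold water 1 (median 0.11), cold water 3 (0.19) or control 2 (0.51), and the Paneth call without cold water 1 (0.023), control 2 (0.19) or control 3 (0.11).

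Genes of mitochondrial energy production were slightly lower in most members, but the libraries of the groups overlapped. Of 51 nuclear-encoded oxidative phosphorylation genes, 48 were lower, with a median of -0.17. The complex I subunits Ndufa5 (81.9 ± 4.06 against 103 ± 9.71 CPM, SD, n = 3) and Ndufb10 (166 ± 19.7 against 206 ± 3.85 CPM) and the complex IV subunits Cox7c (-0.31) and Cox5a (-0.32) led. All 15 mitochondrially encoded genes were lower (median -0.20; mt-Nd3 at -0.33, mt-Rnr1 at -0.35), as were 47 of 52 ribosomal protein genes (median -0.14; Rps28 at -0.35, Rps12 at -0.42). Of 30 genes of fatty acid oxidation and PPAR alpha targets, 24 were lower (median -0.14), with the acyl-CoA dehydrogenase Acadm at -0.36, Acot1 at -1.29 and Pdk4, a brake on glucose oxidation, higher at 0.73. No member of these 4 lists passed over all genes or when adjusted over the list alone. Camera called oxidative phosphorylation (adjusted p = 1.04e-06), ribosomal proteins (adjusted p = 0.000192), fatty acid oxidation (adjusted p = 0.00578) and mitochondrially encoded genes (adjusted p = 0.0109), none of them with a fitted correlation (adjusted p = 0.993 with an estimated correlation for each). With 1 library left out, oxidative phosphorylation stayed called with the preset correlation in 6 of 6 fits (median -0.25 to -0.11). With an estimated correlation it was called in 0 of these 6 fits (adjusted p = 0.755 to 0.996). Relative to all 6 libraries, the mean of this list was -0.14, -0.026 and -0.076 in cold water 1, 2 and 3. It was 0.21, -0.097 and 0.13 in control 1, 2 and 3. The mean of the mitochondrially encoded genes was -0.31, 0.026 and 0.0061 in cold water and -0.27, 0.061 and 0.49 in control, in the same order. The ribosomal call was lost without cold water 3 (-0.050) or control 1 (-0.0099), fatty acid oxidation without cold water 1 (-0.093) or control 3 (-0.10), and the mitochondrially encoded call without cold water 1 (-0.10) or control 3, where the median turned to 0.058.

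Clock genes were higher in cold water, whose gavage was given at an earlier hour than that of the controls. The hour at which tissue was taken is not given in the sources used here. Gavage hour differed between the groups in every library, so hour and treatment cannot be separated for these genes or for any other. Of 18 measured, 14 were higher, with a median of 0.32. The period gene Per1 had 31.3 ± 8.32 CPM in cold water and 15.4 ± 1.56 CPM in controls (SD, n = 3). The clock output gene Tef had 106 ± 30.3 and 63.8 ± 12.2 CPM, Per2 differed by 0.76 and the repressor Nfil3 by -0.75. None passed over all genes and Per1 passed when adjusted over the list alone. Camera called the list (adjusted p = 0.0114; adjusted p = 0.993 with an estimated correlation), and the call was lost without cold water 3 (median 0.031) or control 2 (0.34). Genes of lipid absorption (24 of 32 higher, median 0.13) also passed camera (adjusted p = 0.0487; adjusted p = 0.993 with an estimated correlation). The triglyceride-synthesis enzyme Dgat2 stood at 483 ± 237 against 209 ± 68.8 CPM and the cholesterol exporter Abca1 at 78.9 ± 46.9 against 39.2 ± 3.73 CPM. No lipid gene passed over all genes or when adjusted over the list alone, and the call was lost without cold water 2 (0.18), cold water 3 (-0.11), control 1 (0.15) or control 2 (0.015).

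Groups that mark blood, connective tissue and fat also passed camera. All 6 measured red blood cell genes were higher (median 0.99, adjusted p = 0.000128; adjusted p = 0.993 with an estimated correlation). The globin gene Hbb-bs stood at 118 ± 12.5 against 58.2 ± 39.6 CPM (SD, n = 3) and Hba-a1 at 74.3 ± 16.1 against 38.6 ± 26.9 CPM. Their median was 0.58 without control 3 and 1.72 without control 2. The mean of the red blood cell list relative to all 6 libraries was 0.22, 0.62 and 0.77 in cold water 1, 2 and 3. It was -0.72, 0.43 and -1.32 in control 1, 2 and 3, so control 2 lay above cold water 1. Of 25 fibroblast and matrix genes 22 were higher (median 0.31, adjusted p = 0.0168; adjusted p = 0.993 with an estimated correlation), among them the proteoglycan gene Bgn (0.59) and the collagen gene Col6a2 (0.65). The call was lost without cold water 1 (0.20), cold water 2 (0.14) or control 3 (-0.071). The means of the list (0.44, 0.52 and -0.35 in cold water 1, 2 and 3 and -0.16, 0.65 and -1.09 in control 1, 2 and 3) had the order of the smooth muscle means, which ran from 1.20 in control 2 to -1.60 in control 3. Of 16 adipose genes 14 were lower (median -0.93, adjusted p = 0.0160; adjusted p = 0.993 with an estimated correlation), among them the imprinted gene Nnat (-0.89) and the fatty acid binding gene Fabp4 (-1.15). The call was lost without cold water 1 (-0.65), cold water 3 (-0.61), control 1 (-0.53) or control 2 (-0.84), and the median was -1.95 without cold water 2 and -1.35 without control 3. The mean of the list was high in control 1 (2.01), control 2 (1.78) and cold water 2 (1.59) and low in the other 3 libraries, so it did not follow the groups. No member of these 3 lists passed over all genes or when adjusted over the list alone.

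The remaining groups did not pass camera. Tight and adherens junction genes had a median of 0.030 (15 of 29 higher, adjusted p = 0.841), with alpha-catenin (Ctnna1) at 0.60. Goblet cell and mucus genes had a median of 0.10 (adjusted p = 0.673), small intestinal enterocyte genes 0.12 (adjusted p = 0.168), stem and crypt genes 0.028 (adjusted p = 0.758) and cell cycle genes 0.11 (adjusted p = 0.437). Enteroendocrine genes had a median of -0.094 (adjusted p = 0.673), enteric neuron genes -0.077 (adjusted p = 0.841), tuft cell genes 0.071 (adjusted p = 0.680) and smooth muscle genes 0.10 (adjusted p = 0.538). Among 14 genes of serotonin and tryptophan metabolism (median -0.075, mean 0.26, adjusted p = 0.841), the serotonin transporter Slc6a4 had 74.4 ± 6.01 against 117 ± 17.4 CPM (SD, n = 3). The aryl hydrocarbon receptor Ahr had 11.9 ± 2.31 against 7.43 ± 0.236 CPM and its target Cyp1a1 120.3 ± 119.7 against 19.1 ± 13.1 CPM. None of the 14 passed over all genes or when adjusted over the list alone. Among water and ion transport genes (median 0.090, adjusted p = 0.612), Aqp8 (log2 difference -1.95) passed when adjusted over the list alone and not over all genes, and the bicarbonate cotransporter Slc4a7 stood at 1.63. Cold-inducible and cold-sensing genes (median 0.074, 7 measured, adjusted p = 0.917) did not pass. Neither did heat shock genes (0.10, adjusted p = 0.612), with the chaperone Hsp90aa1 at 0.63, thermogenesis genes (-0.18, adjusted p = 0.200), with the coactivator Ppargc1a at -0.42, or hypoxia genes (0.25, adjusted p = 0.239), with Ndrg1 at -0.85 and Ankrd37 at 1.63. Of the other lists tested, cholesterol and fatty acid synthesis (median 0.19, 24 of 31 higher, adjusted p = 0.0704) came nearest to passing, with the desaturase Scd2 at 1.03. In all, 16 of 47 lists passed camera with the preset correlation, 9 up and 7 down, where 0 passed with an estimated correlation and 0 passed fry, whose smallest adjusted p was 0.603.

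**Figure D4:**
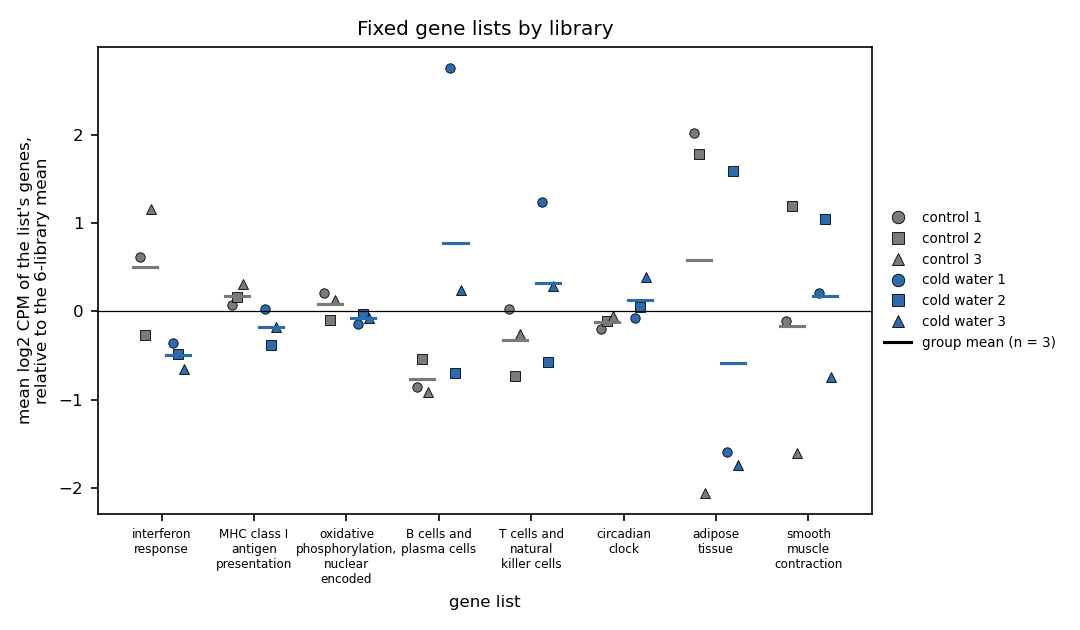
Mean log2 CPM of the genes of 8 fixed lists in each of the 6 libraries, relative to the mean of all 6, cold water in blue and control in grey, with group means as bars. The interferon list lay at -0.36 to -0.65 in cold water and at -0.27 to 1.15 in controls, and the B cell list reached 2.75 in cold water 1.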

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

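DESeq2, summing by gene ID, counts divided by the worth of a fragment, and library totals without scaling factors were alternatives chosen after seeing the data. edgeR and camera called 5 genes, 6 transcripts and 16 lists, the choice of test and its variance model moved these counts most, and the causes of the differences below were not tested. Genes called numbered 3 with limma on log2(FPKM + 1), with pseudocounts of 0.1 and 0.5 and with robust variance (3 rose and 0 fell, against 2 and 3 with edgeR), and 2 without the trend. They numbered 48 with limma and library weights (28 rose and 20 fell), and 3 with limma on values rescaled to a fixed total without mitochondrial genes (3 rose and 0 fell), as many as with limma alone. With edgeR they numbered 3 with no filter, 3 without scaling factors (3 rose and 0 fell) and 1 with the most abundant transcript of each gene, and with DESeq2 71 (37 rose and 34 fell). With limma and quantile normalization 4 genes were called (3 rose and 1 fell), and 4 with edgeR on counts divided by the worth of a fragment, where the call of Gm22758 was lost; with at least 5 FPKM, median-of-ratios scaling, a threshold of 0.1 and summing by gene ID the count was 5. Transcripts called numbered 23 with limma on log2(FPKM + 1), 22 and 26 with pseudocounts of 0.1 and 0.5, 35 without the trend, 24 with robust variance, 33 with limma and library weights, 0 with no filter, 2 without scaling factors, 28 with limma on values rescaled to a fixed total, 28 with limma and quantile normalization and 585 with DESeq2. Lists called numbered 9 with limma and library weights, 0 with an estimated correlation and 0 with fry, and 11 to 17 under the other alternatives. Limma on log2(FPKM + 1) lost the calls of macrophages and dendritic cells (adjusted p = 0.0662), cytokines, chemokines and NF-kB targets (adjusted p = 0.0614), lipid absorption and lipoprotein assembly (adjusted p = 0.0601) and fibroblasts and extracellular matrix (adjusted p = 0.0718), which passed in 9, 10, 10 and 12 of 25 alternatives.

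With each of the 6 libraries left out in turn, 0 to 1 genes, 0 to 10 transcripts and 12 to 15 lists were called, with fewer samples in the fit. The 1 gene was Tmem254a, without cold water 1, and the 10 transcripts came without control 3. The log2 differences of genes named in advance, none of which passed, turned sign in some of these fits, with ranges of -0.017 to 0.42 for Rbm3, -0.024 to 0.36 for Cldn2, -0.22 to 1.08 for Reg3g, -0.82 to 0.021 for Cck, -0.16 to 0.32 for Ocln, -0.15 to 0.38 for Lct, -0.21 to 0.21 for Sis, -0.36 to 0.46 for Cirbp, -0.19 to 0.18 for Slc5a1 and -0.57 to 0.29 for Muc2. Among lists that passed, medians that turned sign ranged from -0.11 to 0.30 for lipid absorption and lipoprotein assembly, -0.071 to 0.86 for fibroblasts and extracellular matrix and -0.36 to 0.058 for mitochondrially encoded genes. Of the lists that did not pass with all libraries, smooth muscle contraction was called higher without cold water 3 (median 0.43) and control 2 (1.01) and lower without control 3 (-0.39), with adjusted p = 0.903, 0.900 and 0.908 with an estimated correlation. Small intestinal enterocytes were called without cold water 1 or control 3, with adjusted p = 0.907 and 0.908 with an estimated correlation. Other such calls by camera without cold water 1 included immediate early genes (median 0.26, adjusted p = 0.00166) and hypoxia (0.31, 0.00399), both higher. They also included xenobiotic and glutathione metabolism, higher (0.14, 0.0334), and cell cycle genes, lower (-0.12, 0.00721). Each of these lists had an adjusted p = 0.907 with an estimated correlation.

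Muc2 had a log2 difference of 0.050. It was -0.051 with limma on log2(FPKM + 1), without the trend and with robust variance, -0.0518 and -0.0516 with pseudocounts of 0.1 and 0.5, -0.54 with library weights, -0.0061 without scaling factors and -0.0365 with limma on values rescaled to a fixed total. With limma and library weights, Rbm3 was -0.16, Cldn2 -0.022, Ocln -0.38 and Slc5a1 -0.081, and the list medians were -0.15 for Paneth cells and epithelial antimicrobials, -0.24 for T cells and natural killer cells, -0.013 for macrophages and dendritic cells and 0.13 for mitochondrially encoded genes. With the most abundant transcript of each gene, Tjp1 was -0.028, Tph1 -1.23 and Cirbp 0.18. The 5 called genes kept their direction under every alternative in which they were tested, and passed in 16 of 24 for Tspan14, 14 of 24 for Gm22758, 9 of 24 for Ap1ar, 8 of 24 for Col4a3bp and 6 of 23 for Gm15743. Their log2 differences ranged from 1.80 to 5.54 for Tspan14, 3.30 to 7.54 for Gm22758, -1.94 to -1.62 for Ap1ar, -3.21 to -1.01 for Col4a3bp and -3.78 to -1.52 for Gm15743.

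Whether replicate numbers pair the libraries stays open. Deviations from the group means correlated at -0.02, 0.21 and 0.41 for numbers 1, 2 and 3. Cold water 2 and cold water 3 correlated best with the control of their own number. Cold water 1 correlated best with control 2 (0.18). With the replicate number as a block, 0 genes, 0 transcripts and 17 lists were called, Cirbp was 0.059 and Muc2 -0.051. As the mean of log2(FPKM + 1) back on the FPKM scale, in place of the median of the list, the segment marker lists stood at 456 for enterocytes, 5.04 for colon, 35.5 for ileum and 6.36 for duodenum. The sum over transcripts with a reference ID alone was not run, as the table holds no other transcripts. Depth limits the low genes most: Gm22758 had 1 count in each control library, and 54.3 to 59.6% of transcripts had a count of 0.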

Other observations

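The tests on splits of the libraries, on isoform reassignment, on cell shares, on single libraries and on follicular B cell genes were chosen only after the result was seen. Those on the leading isoform and on the epithelium over follicles were set before. Fat and muscle wall genes varied between libraries far more than between groups. The mean of 16 adipose genes, relative to all 6 libraries, was 2.01 and 1.78 in control 1 and control 2 and 1.59 in cold water 2, against -1.59, -1.74 and -2.05 in cold water 1, cold water 3 and control 3. The adipokine gene Adipoq had 22.0, 13.4 and 10.1 CPM in the first 3 of these libraries and a count of 0 in the other 3, and the carbonic anhydrase gene Car3 of fat and muscle had 84.8, 66.4 and 41.0 CPM against 1.42, 0.324 and 0.555 CPM. The smooth muscle list stood at 1.20 in control 2 and 1.05 in cold water 2 and at -1.60 in control 3.

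Immunoglobulin variable genes moved with the fixed B cell list. Of 144 measured immunoglobulin variable genes, 138 were higher in cold water, 52 at an unadjusted p under 0.05 and 0 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with a median of 3.57-fold. Without cold water 1, 121 of 144 were higher and the median log2 difference was 0.61.

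Splits of 3 libraries against 3 number 10, too few for a share under 0.05. The groups called 5 genes and the highest other split 5, and 2 of 10 splits called as many. That other split, cold water 1 and cold water 3 and control 3 against the rest, called Adipoq, Car3, Cbl, Cfd and Retn, 4 of them fat genes, and it is the split by adipose level described above. For lists the groups called 16 and the highest other split 27, and 8 of 10 splits called as many.

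The transcript calls may come from reads of a gene assigned to another of its isoforms. The median gene-level log2 difference of the 5 genes whose called transcript fell was 0.087, which is what such a reassignment would give, although 0610005C13Rik was lower as a gene (-0.88). At Marchf8 and Rnaset2b a partner isoform took the place of the called one. Leading isoforms that were one transcript in 3 libraries and another in the other 3 numbered 61 genes between the groups and at most 57 in another split, so isoform estimates that flip in any grouping and an effect of cold water on splicing or promoter use cannot be told apart, for lack of libraries. In the splits, 2 of 10 called as many transcripts as the 6 of the groups, and the highest other called 10.

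The lower interferon response list in cold water is a candidate effect of the treatment, and several other accounts were tested. Fewer immune cells would lower their markers, but the lowest median of the B cell, T cell and macrophage lists with any 1 library left out was 0.0022. A smaller share of epithelium would lower the enterocyte list as much, but its lowest median was -0.087. The interferon median was at most -0.74 with any 1 library left out, so it did not rest on 1 control library alone. The list mean was high in both control 1 (0.61) and control 3 (1.15), so leaving out either keeps the other. Control 2 (-0.27) lay near cold water 1 (-0.36), so the difference was not shared by all controls. In the splits, 2 of 10 gave an absolute median as large, with 1.05 for the groups and 1.11 for the highest other, which set cold water 1, control 1 and control 3 against the rest. Chance in how the libraries fell into groups therefore stays open, and so does a difference between animals or cages in exposure to viruses or microbes, which the labels do not describe and which was not tested. The hour of gavage differed with the treatment in every library and cannot be told apart from it.

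The higher B cell and immunoglobulin genes in cold water came mainly from 1 library, since the median of the list fell to 0.45 without cold water 1. A lymphoid follicle in that sample is a candidate source: 8 measured follicular B cell genes (6 of them in the fixed B cell list), such as Ms4a1 (32.6 CPM against a mean of 0.472 CPM in the other 5 libraries) and Ighd (59.7 against 0.722 CPM), stood a median of 6.33 above the other 5 libraries on the log2 scale. The 11 measured plasma cell genes (9 in the fixed list), such as Igha (4465 against 1798 CPM), stood 1.34 above, a gap of 4.99. Cold water 1 had been singled out by genes of the same fixed list, so this contrast is no independent support for a follicle. The follicular genes had means of 0.124 to 0.797 CPM in the other 5 libraries, near the floor. Those of the plasma cell genes ran from 0.776 CPM (Tnfrsf17) to 1798 CPM (Igha). Epithelium over follicles, 7 measured genes that other epithelium also expresses and 1 of which is in another fixed list, stood 0.75 above, with Spib at 1.76 and Ubd at 1.71, which lies between what a follicle and its absence were set to give, so these cannot be told apart from that list. In the splits, 1 of 10 (the groups themselves) gave a median as large, with 2.38 for the groups and 2.21 for the highest other.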
